A study of Homo sapiens with 8 samples.

How the data were processed

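The series holds 8 inDrops droplet libraries of TF-1 cells, a human erythroleukaemia line, with 2 libraries in each of 4 groups given by 2 genotypes and 2 treatments. The genotypes are wild-type IDH (wt) and mutant IDH2 with the R140Q substitution (R140Q). The treatments are PBS and IL-1β at 20 ng/mL, each for 3 h. The labels call the libraries of a group biological replicates, and the p-values below measure spread between these libraries. The labels do not say how many independent lines carry each genotype, so line and mutation cannot be separated here.

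Each deposited matrix holds raw counts of molecular identifiers per gene and cell barcode, which were used without rescaling. The other deposited files list the cell barcodes and the genes (Ensembl identifier and symbol) that name the matrix columns and lines. The processing notes of the authors name Bowtie 1.1.1 and the mouse build GRCm38, although the gene identifiers are human, and the notes of the annotation release and of the barcode filter are not given in the sources used here. The 8 gene files were identical, with 58219 genes. Of their symbols, 275 were shared by more than 1 gene, and these genes were kept apart by identifier. For 7 libraries all 147456 barcode combinations were listed. Replicate 2 of the R140Q IL-1β group listed 2510 barcodes, none below 302 UMIs, so it had been filtered beforehand.

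Barcodes with 1000 UMIs or more were taken as cells, without a mitochondrial filter and with doublets kept, and their counts were summed per library. The sums ranged from 1617539 to 6035021 UMIs. Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 11388. Counts were scaled by TMM. A quasi-likelihood model with 1 coefficient per group was fitted to all 8 libraries (glmQLFit and glmQLFTest), so that groups of 2 share 1 estimate of the spread (common dispersion 0.00567). Levels are in CPM (counts scaled to a common library total) with the SD over 2 libraries. Log2 fold changes carry the standard error of the model, and the default prior count of edgeR enters them. P-values are 2-sided and Benjamini-Hochberg adjusted over all genes tested. A gene is called at an adjusted p under 0.05. Single measures per library, such as shares of cells, are given without a test: an exact test of 2 libraries against 2 cannot give a p below 0.333, and no model over all 8 libraries was fitted to them. A fold against a group with 0 counts is a lower bound computed with 3 counts over that group, and with 1 to 3 counts the ratio of summed counts is given with its exact 95% counting interval. The fitted log2 change of such genes depends on the prior count.

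The comparisons were IL-1β against PBS in each genotype, the difference of these responses (the interaction of genotype and treatment), R140Q against wt in each treatment, and the average effects of treatment and of genotype over 4 libraries against 4 with the other factor in the model. The comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. In the IL-1β comparisons, their difference and the genotype comparison in PBS, the rule names the 10 largest increases and the 10 largest decreases among called genes with a mean of 20 CPM or more whose groups do not overlap (the last condition not for the difference), or the 5 smallest p-values if fewer than 5 genes pass. It adds up to 4 members with the smallest p of each list described, and IDH1, IDH2, IL1R1, IL1RAP, NFKBIA, TNFAIP3 and CXCL8. Genes named outside the rule are said to have been chosen after their values were seen.

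The 29 gene lists were NF-kB targets and feedback, cytokines and chemokines, the IL-1 receptor pathway, immediate early and AP-1 genes, interferon-stimulated genes, antigen presentation, erythroid, megakaryocyte, myeloid and monocyte, mast cell and basophil, stem, progenitor and leukaemia genes, GM-CSF and cytokine signalling, lymphocyte genes, fibroblast and epithelium genes, the TCA cycle and IDH, 2-oxoglutarate-dependent dioxygenases, DNA methylation and histone modifiers, glycolysis and hypoxia, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, cholesterol synthesis, ATF4 and the unfolded protein response, heat shock, apoptosis and the BCL2 family, p53 targets, S phase, G2 and M phase, MYC and ribosome biogenesis, and glutathione and NRF2. Each list with 5 or more tested members was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation and with fry, which tests whether the members move on balance one way, and in a second form whether they move either way. For each list the called members are given over all genes and adjusted over the list alone.

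Shares of cells with a UMI of a gene were taken after thinning every cell to 1000 UMIs, with exact (Clopper-Pearson) 95% intervals, which cover counting error only. Cells were normalised, reduced to 2000 variable genes and 30 components, and grouped by Leiden clustering at resolution 0.5 with 15 neighbours (scanpy 1.11.5, igraph 0.11.9), without integration. Cell cycle phases were scored with the S and the G2 and M lists. Free RNA was measured in barcodes with 5 to 100 UMIs. For the scan along chromosomes, which was chosen after the genotype calls were seen, 5902 genes on chromosomes 1 to 22 with 20 CPM or more were placed by GENCODE coordinates on GRCh38 and read in 116 runs of 50 neighbouring genes (the last of a chromosome at least 30). The median log2 difference of a run was set against 10000 random sets of as many genes, and a run stood out when it fell in the outer 0.1%, with both tails together.

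The alternatives were median-of-ratios size factors, DESeq2 1.42.0, no low-count filter, minimums of 500 and 2000 UMIs, at most 20% mitochondrial UMIs, Scrublet doublets left out (expected rate 5%, with a threshold for wt IL-1β replicate 2 that moved with the number of computing threads, here 1), all libraries thinned to the smallest, a block for the replicate number, the libraries compared alone, and each library left out in turn, in which case the lone library of its group is assumed to vary like the others. The replicate numbers are not said to mark a shared day, so the block is an alternative only. Shares of cells, phases, clusters and the correlation of the responses had their own alternatives. The model was tested on simulated data with 50 changed genes at each planted fold. Of planted changes in genes with 20 CPM or more, it recovered 67.9% at 1.5-fold and 100% at 2-fold for IL-1β in wt. For the difference of responses it recovered 21.4% and 84.8%. So many changed genes ease the adjusted threshold, and these shares do not hold where few genes change. The scan was tested as well, with gene positions shuffled, and 5 of 5 planted runs were found and 0 others in 10 scans. Runs were planted at 1 size only, close to that of the lower runs reported on chromosome 20. Smaller shifts, such as those of the other runs reported, were not planted. Shuffling removes any likeness of neighbouring genes, so the 0 others do not speak to runs that such likeness could give. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps. Sequence variants were not examined, because 3′ counts per gene cannot show the substitution. No library was left out of the main values.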

Results

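Single-cell RNA was measured in TF-1 cells, an erythroleukaemia line that grows on GM-CSF, with wild-type IDH (wt) or with IDH2 R140Q, the mutant mitochondrial isocitrate dehydrogenase that makes 2-hydroxyglutarate. Cells of each genotype received PBS or IL-1β (20 ng/mL) for 3 h, with 2 libraries in each of the 4 groups and 8 in all. The 14382 cells were spread unevenly. The wt libraries held 1276 and 2056 cells in PBS and 792 and 1312 with IL-1β, and the R140Q libraries held 2337 and 3033 in PBS and 1741 and 1835 with IL-1β. Their summed counts were 2926046 and 6035021 UMIs for wt in PBS, 1617539 and 3222397 for wt with IL-1β, 4524986 and 5399876 for R140Q in PBS, and 2451293 and 3056665 for R140Q with IL-1β. The median depth per cell was lowest in R140Q IL-1β replicate 1, at 1293 UMIs, and highest in wt PBS replicate 2, at 2738 UMIs. The first component of the libraries, with 38.4% of the variance, parted the treatments, and the next, with 27.6%, parted the genotypes. Every value below is in CPM or log2 of a ratio unless stated, with the SD over n = 2 libraries or the standard error (SE) of the edgeR model, and p-values are edgeR adjusted p-values.

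The first comparison asks what IL-1β does to wt cells. NFKBIA, TNFAIP3 and CXCL8 rose, and KLF1 fell. NFKBIA, which encodes the inhibitor IκBα (ENSG00000100906.10, GRCh38 chromosome 14, 35401511 to 35404749), rose from 35.5 ± 5.63 to 352 ± 22.8 CPM, 10.2-fold (log2 3.34 ± 0.13, adjusted p = 1.41e-14). TNFAIP3, which encodes the ubiquitin-editing enzyme A20 (ENSG00000118503.14, chromosome 6, 137867188 to 137883312), rose 23.7-fold. CXCL8, the chemokine interleukin-8 (ENSG00000169429.10, chromosome 4, 73740506 to 73743716), rose 82.7-fold from 1.16 ± 0.229 to 103 ± 2.67 CPM. CXCL1, its neighbour on chromosome 4 (ENSG00000163739.4, 73869393 to 73871242), went from 1 count to 1151 counts over both libraries, a ratio of 2220 with a counting interval of 398 to 87800. KLF1, the erythroid transcription factor (ENSG00000105610.4, chromosome 19, 12884422 to 12887199), fell from 121 ± 18.1 to 58.3 ± 7.21 CPM (log2 −1.06 ± 0.16, adjusted p = 0.00011).

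Of 11388 genes tested, 519 were called, 379 higher and 140 lower, and 177 of the increases and 24 of the decreases were 2-fold or more. At a mean of 20 CPM or more, the 10 largest increases were those of TNFAIP3, CXCL8 and CXCL1 above and of BIRC3 (an inhibitor of apoptosis, 104-fold), CXCL3 (82.4-fold), TNFRSF9 (a costimulatory receptor, 76.5-fold), PTGS2 (the inducible cyclooxygenase, 13.8-fold), NFKBIZ (13.0-fold), ICAM1 (an adhesion molecule, 11.8-fold) and CXCL2, whose ratio was 114 (38.5 to 560) against 3 counts in PBS. The largest decreases were that of KLF1 above (log2 −1.06) and those of ERMAP, an erythroid membrane protein (−1.12), NINJ2 (−1.06) and DAG1 (−0.89). With them were SESN1, CDC42EP4, SOX18, CMPK2, SDHAF1 and APOL4. The last 6 lost their call when 1 library was left out. Those were SESN1 (adjusted p = 0.335) and APOL4 (0.316) without wt IL-1β replicate 2, and SDHAF1 (0.0609) without wt IL-1β replicate 1. They were also CDC42EP4 (0.0524) and SOX18 (0.08) without wt PBS replicate 2, and CMPK2 without either wt PBS replicate 2 (0.0743) or wt IL-1β replicate 2 (0.116). The other 14 of the 20 named by size kept theirs without each library. The count itself fell to 245 without wt PBS replicate 2.

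**Figure D1:**
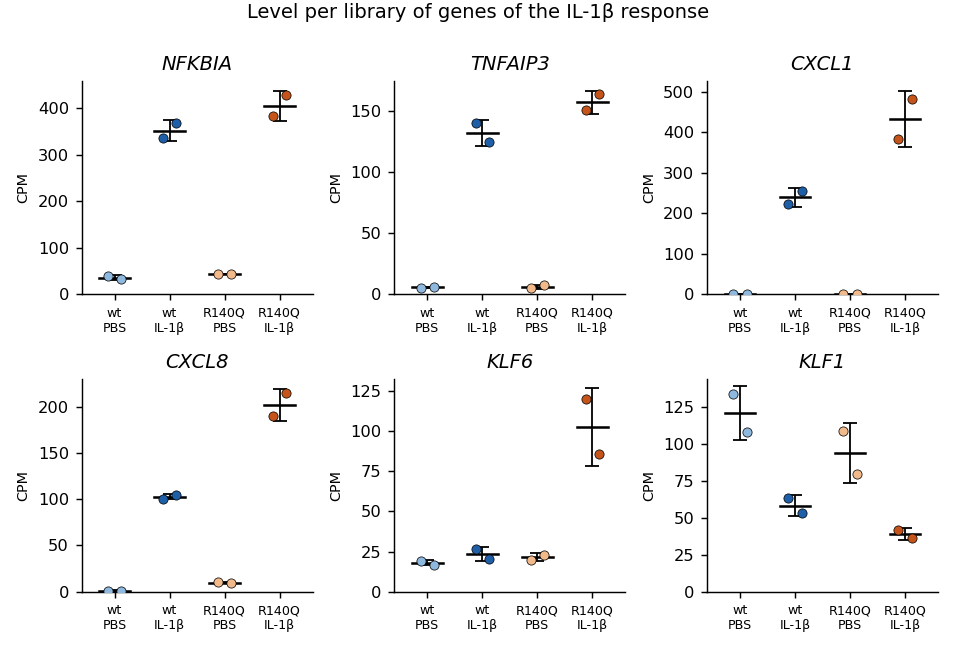
Level in CPM (vertical axes, linear, from 0) of 6 genes in the 4 groups; points are the 2 libraries of a group, the bar is their mean and the whisker their SD. NFKBIA, TNFAIP3, CXCL1 and CXCL8 were higher with IL-1β in both genotypes, KLF6 reached 103 CPM in R140Q cells against 23.5 CPM in wt cells, and KLF1 was lower with IL-1β in both.

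The gene lists place these changes. Of 36 NF-kB targets and feedback genes tested, 25 rose and 0 fell (27 and 0 adjusted over the list alone, camera adjusted p = 3.48e-149), with TNFRSF9, TNFAIP3, ICAM1 and BIRC3 first by p. Of 20 cytokines and chemokines, 14 rose (16 adjusted over the list alone, camera adjusted p = 3.54e-94), among them IL1A, which encodes IL-1α and rose 11.2-fold. Of 30 immediate early and AP-1 genes, 13 rose (18 adjusted over the list alone, camera adjusted p = 3.48e-14), with BTG2 (log2 2.56), DUSP6 (2.24), JUN (1.94) and JUND (0.97). These are the 3 of 9 called lists that held with an estimated correlation, at an adjusted p of 0.00326, 0.00326 and 0.0169.

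The other lists called by camera at the preset correlation follow. In the erythroid list 1 of 38 members rose and 5 fell (3 and 11 adjusted over the list alone, camera adjusted p = 0.00284, adjusted p = 0.182 with an estimated correlation): KLF1, NFE2 (log2 −0.87) and TAL1 (−0.56), all erythroid transcription factors, fell, and CA2, a carbonic anhydrase, rose (1.32). TAL1 lost its call without wt PBS replicate 2 (adjusted p = 0.113). In GM-CSF and cytokine signalling 5 of 18 rose and 0 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.182 with an estimated correlation), with the kinase PIM2 (1.76), the inhibitor SOCS1 (1.38) and the receptor chain IL6ST (1.00). In cholesterol synthesis 1 of 25 rose and 2 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.182 with an estimated correlation), with MSMO1 at −0.76. In heat shock 1 of 21 rose (3 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.363 with an estimated correlation): HSPA6, an inducible chaperone, at 3.01. In p53 targets 5 of 19 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0457, adjusted p = 0.222 with an estimated correlation), with the antiproliferative gene BTG2 and the proapoptotic gene BBC3 (1.17). In glutathione and NRF2 3 of 21 rose (4 adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.189 with an estimated correlation), with the cystine carrier SLC7A11 (0.85) and malic enzyme ME1 (0.69).

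The other lists did not pass. In the IL-1 receptor pathway 4 of 29 rose and 0 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.319), including the kinase IRAK2 (log2 4.90) and the IL-33 receptor IL1RL1 (2.21). IL1RAP, the accessory chain of the IL-1 receptor, had a log2 change of 0.57 ± 0.22 (adjusted p = 0.148), and IL1R1 had too few counts to be tested. Among interferon-stimulated genes 1 of 26 rose and 2 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.163). In antigen presentation 1 of 21 rose (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.233), namely HLA-E (0.90). The megakaryocyte list had 2 of 10 higher (2 adjusted over the list alone, camera adjusted p = 0.494), with THBS1 at 3.21. In the myeloid and monocyte list 2 of 15 rose (2 up and 2 down adjusted over the list alone, camera adjusted p = 0.965). The mast cell and basophil list had 1 of 8 higher (1 adjusted over the list alone, camera adjusted p = 0.185). It is the transcription factor GATA2 (0.69). In the stem, progenitor and leukaemia list 3 of 19 rose, GATA2 and the adhesion receptor CD44 (1.37) among them, and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.841). In the TCA cycle and IDH list 1 of 32 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.494). IDH1, the cytosolic isocitrate dehydrogenase (ENSG00000138413.13), went from 70.9 ± 6.98 to 43.1 ± 3.81 CPM (log2 −0.71 ± 0.14, adjusted p = 0.0024), a call that ended without wt PBS replicate 2 (0.0705). IDH2 stood at −0.08 (adjusted p = 0.86).

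The 2-oxoglutarate-dependent dioxygenases had 1 of 32 higher and 1 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.743). DNA methylation and histone modifiers had 2 of 25 higher (3 adjusted over the list alone, camera adjusted p = 0.743), with the methyltransferase KMT2A at 0.92. In glycolysis and hypoxia 2 of 29 rose (5 up and 1 down adjusted over the list alone, camera adjusted p = 0.144), with DDIT4, an mTOR inhibitor, at 1.62. Of 40 nuclear oxidative phosphorylation genes 1 rose (0 adjusted over the list alone, camera adjusted p = 0.272). Of 13 mitochondrially encoded genes 1 rose (1 adjusted over the list alone, camera adjusted p = 0.104). ATF4 and the unfolded protein response had 4 of 30 higher (5 adjusted over the list alone, camera adjusted p = 0.0917). Apoptosis and the BCL2 family had 3 of 22 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.233). S phase had 0 of 43 in either direction (0 adjusted over the list alone, camera adjusted p = 0.33). G2 and M phase had 3 of 53 higher (3 adjusted over the list alone, camera adjusted p = 0.593). MYC and ribosome biogenesis had 1 of 30 higher (0 adjusted over the list alone, camera adjusted p = 0.104). The lists of other cell types had 4 tested members each and no camera test. IGKC, an immunoglobulin chain, rose among lymphocyte genes (1 adjusted over the list alone), at least 24.4-fold with 38 counts against 0. COL6A3, a collagen, rose among fibroblast and epithelium genes (3 adjusted over the list alone), with levels of 69.6 and 22.3 CPM in the wt IL-1β libraries. The call of COL6A3 ended without wt PBS replicate 2 (adjusted p = 0.0861). Median, mean and test differed in sign for the IL-1 receptor pathway (median −0.04, mean 0.27, test up), megakaryocyte (−0.13, 0.16, up), myeloid and monocyte (−0.04, 0.23 with the fitted value of VCAN, up), stem, progenitor and leukaemia (−0.15, −0.13, up) and DNA methylation lists (−0.05, 0.02, up).

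The same comparison in R140Q cells asks whether mutant cells respond. NFKBIA rose from 42.8 ± 0.616 to 406 ± 32.4 CPM (9.47-fold, log2 3.24 ± 0.12, adjusted p = 8.89e-15), TNFAIP3 rose 25.7-fold and CXCL8 20.5-fold, from 9.88 ± 0.49 to 202 ± 17.2 CPM. CXCL1 went from 1 count to 2318 counts, a ratio of 4450 (797 to 176000). KLF6, a zinc-finger transcription factor of the immediate early class (ENSG00000067082.14, chromosome 10, 3775996 to 3785281), rose 4.75-fold from 21.4 ± 2.48 to 103 ± 24.2 CPM (log2 2.25 ± 0.16, adjusted p = 1.05e-09). KLF1 fell from 94.0 ± 20.4 to 39.2 ± 3.98 CPM (log2 −1.26 ± 0.16).

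In R140Q cells 713 genes were called, 479 higher and 234 lower, with 242 and 38 at 2-fold or more. The other leading increases were CXCL2 (154-fold), BIRC3 (log2 6.61), CXCL3 (71.7-fold), TNFRSF9 (63.8-fold), PTGS2 (18.2-fold), PHLDA1 (14.8-fold) and NFKBIZ (13.6-fold). Leading decreases besides KLF1 were SOX18, an endothelial transcription factor (log2 −1.22), VANGL1 (−1.14), GYPE, a glycophorin (−1.11), APOL4 (−0.98), CMPK2 (−0.97), FAM212A (−0.93) and NFE2 (−0.92). ERMAP and the erythropoietin receptor EPOR fell to 0.501 of their PBS level. Without R140Q IL-1β replicate 2 the calls of EPOR (adjusted p = 0.171), NFE2 (0.0769), CMPK2 (0.0641) and APOL4 (0.0597) ended, and that of FAM212A ended without R140Q PBS replicate 2 (0.0528) and without R140Q IL-1β replicate 1 (0.0771). The count fell to 344 without R140Q PBS replicate 1, 360 without R140Q PBS replicate 2, 376 without R140Q IL-1β replicate 1 and 274 without R140Q IL-1β replicate 2.

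By list, 28 of 36 NF-kB targets and feedback genes rose (28 adjusted over the list alone, camera adjusted p = 2.87e-161, 0.000646 with an estimated correlation). So did 15 of 20 cytokines and chemokines (16 adjusted over the list alone, 6.73e-97, 0.000558 with an estimated correlation) and 15 of 30 immediate early genes (19 adjusted over the list alone, 4.12e-18, 0.00478 with an estimated correlation). Of the 8 lists called, 5 did not hold with an estimated correlation. In the erythroid list 2 of 38 rose and 9 fell (4 and 15 adjusted over the list alone, camera adjusted p = 0.00115, adjusted p = 0.0958 with an estimated correlation), with TAL1 at −0.81 and CA2 at 2.11. GM-CSF and cytokine signalling had 6 of 18 higher and 2 lower (8 and 2 adjusted over the list alone, 0.00234, adjusted p = 0.0958 with an estimated correlation), with SOCS1 at 1.71. In p53 targets 7 of 19 rose and 1 fell (8 and 2 adjusted over the list alone, 0.00299, adjusted p = 0.0958 with an estimated correlation), with BTG2 at 1.94. Heat shock had 3 of 21 higher (3 adjusted over the list alone, 0.00299, adjusted p = 0.25 with an estimated correlation), with HSPA6 at 3.47. The mast cell and basophil list had 1 of 8 higher (4 adjusted over the list alone, 0.0489, adjusted p = 0.202 with an estimated correlation), GATA2 at 0.77. The other tested lists had camera adjusted p-values from 0.0502 to 0.852. IDH1 went from 73.6 ± 2.79 to 46.1 ± 5.2 CPM (log2 −0.67 ± 0.13, adjusted p = 0.00202). That call was made in 16 of 18 alternatives (adjusted p from 1.89e-05 to 0.379) and lost at 2000 UMIs (−0.48, 0.379) and without R140Q IL-1β replicate 1 (0.0778). IDH2 stood at 0.04 (adjusted p = 0.948) and IL1RAP at 0.13 (0.773). Among markers of other cell types IGKC rose, at least 16.6-fold with 26 counts against 0. Median, mean and test differed in sign for the IL-1 receptor pathway (−0.06, 0.13, up), interferon-stimulated genes (−0.06, 0.07, down), the TCA cycle and IDH (0.01, −0.02, down) and DNA methylation (−0.02, 0.01, down).

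**Figure D2:**
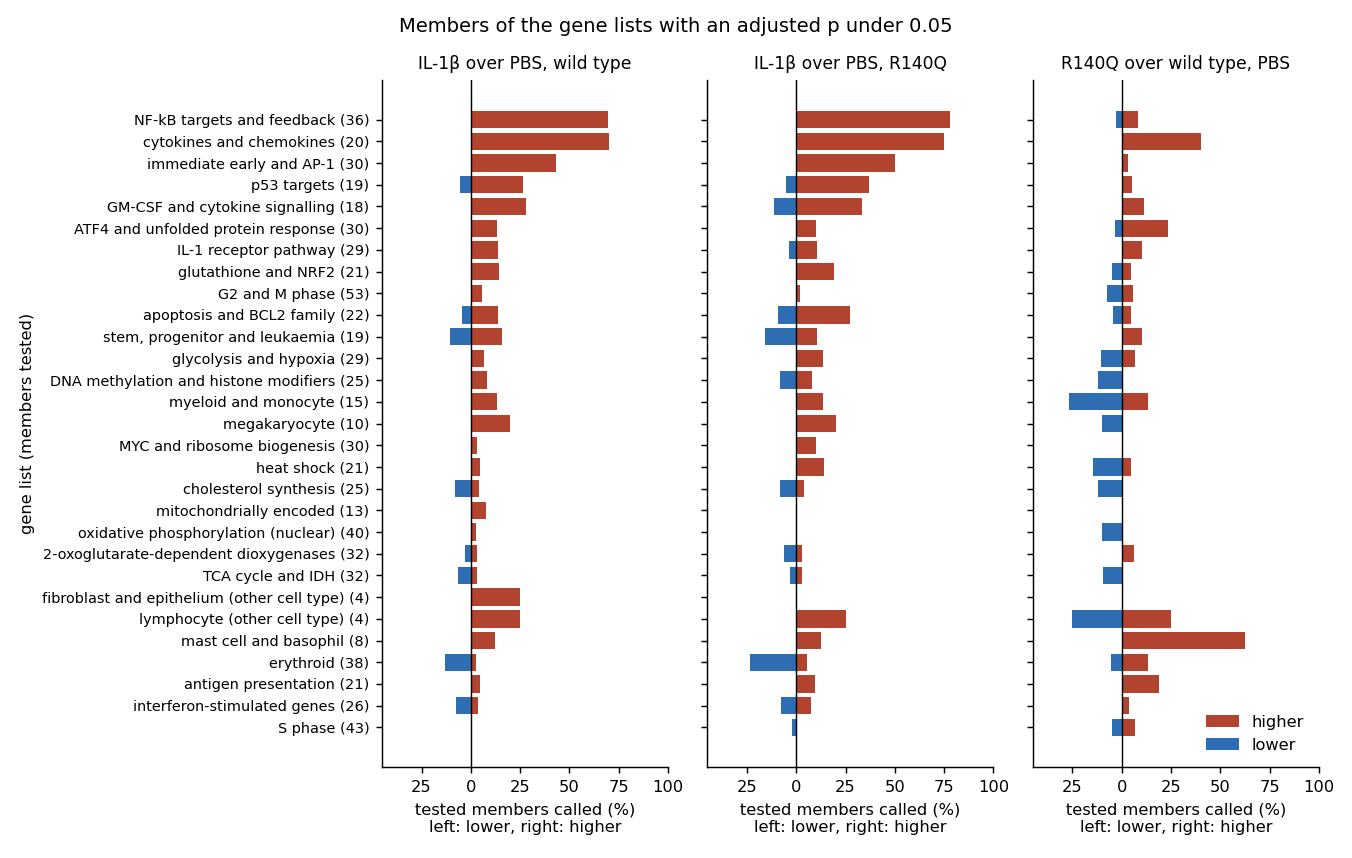
Share of each list's tested members with an adjusted p under 0.05 (horizontal axes, percent, higher to the right, lower to the left) for IL-1β in wt, IL-1β in R140Q and R140Q against wt in PBS; the number of members tested stands beside each list. NF-kB genes (25 and 28 of 36) and cytokines (14 and 15 of 20) lead both IL-1β panels, and mast cell and basophil genes (5 of 8) lead the genotype panel.

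Whether mutant IDH2 changes the response to IL-1β is the question of the series. The difference of the responses compares the lines that carry each genotype. KLF6 responded more in R140Q cells: its log2 change was 2.25 there and 0.36 ± 0.23 in wt cells (edgeR adjusted p = 0.442), a difference of 1.89 ± 0.28 with a 95% interval of 1.32 to 2.46 (edgeR adjusted p = 0.00918), or 3.71-fold. It was the 1 gene of 11388 that passed in edgeR, beside 472 genes at an unadjusted p under 0.05; DESeq2 called 1 gene, with 111 at an unadjusted p under 0.05. The PBS level of CXCL8 was already higher in R140Q cells, where 11 of 2337 and 18 of 3033 cells held a UMI. The CXCL8 response differed the other way, by −2.01 (interval −2.77 to −1.26), and did not pass (edgeR adjusted p = 0.0944). It passed in 4 of 17 alternatives (edgeR adjusted p from 0.0131 to 1). They were no low-count filter (0.0131), 500 UMIs (0.0468), a replicate block (−2.02, 0.0343) and without wt IL-1β replicate 2 (−1.995). The remaining genes of the 5 smallest p-values, named as not passing, were the non-coding gene CH17-373J23.1 (3.13, adjusted p = 0.81), WASF1 (−1.03) and CKS2 (0.67, adjusted p = 0.996).

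NFKBIA and TNFAIP3 responded alike in both genotypes within their intervals. The difference was −0.10 for NFKBIA (interval −0.47 to 0.27), 0.11 for TNFAIP3 (−0.50 to 0.73), and −0.20 for KLF1 (−0.68 to 0.28). For CXCL1, with 1 count in PBS in either genotype, it was open (0.97, interval −3.21 to 5.15). Of 605 genes called for IL-1β in either genotype with 20 CPM or more, 532 had an interval within 1 log2 unit of 0. That bound is wide against most responses. Of all 519 calls in wt, 177 increases and 24 decreases were 2-fold or more, and of 713 in R140Q, 242 and 38. A smaller response could be absent in 1 genotype and still lie within the bound, so equal responses are not shown by it. None of the lists was called by camera (lowest adjusted p = 0.46, for cytokines and chemokines, cholesterol synthesis and G2 and M phase), by the estimated correlation (lowest 0.816) or by fry's test for one direction. Fry's test for members moving either way called immediate early genes (adjusted p = 0.025) and cytokines and chemokines (adjusted p = 0.0434). The list of immediate early genes had 1 called member, KLF6 (1 adjusted over the list alone). Median, mean and test differed in sign for NF-kB targets (0.03, −0.01, up), erythroid (−0.06, 0.01, down), mast cell and basophil (0.09, −0.01, up), stem, progenitor and leukaemia (0.03, −0.01, down), ATF4 genes (−0.01, 0.01, up), antigen presentation (−0.01, −0.02, up) and oxidative phosphorylation (−0.01, 0.00, down). The call of KLF6 ended without R140Q PBS replicate 1 (1.78, adjusted p = 0.149), without R140Q IL-1β replicate 1 (1.64, 0.0914) and without wt PBS replicate 2 (2.00, 0.0938), and at a minimum of 2000 UMIs (1.36, adjusted p = 1) or with libraries thinned to the smallest (1.90, 0.181); over 17 alternatives its adjusted p ranged from 4.71e-09 to 1.

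Across genes, which are not independent replicates, the log2 responses of both genotypes correlated with Pearson r = 0.716 and Spearman rho = 0.49 over all genes, 0.857 and 0.599 over 6113 genes with 20 CPM or more, and 0.962 and 0.962 over the NF-kB list. Of the increases, 278 were called in both genotypes, against 15.9 for independent sets, and of the decreases 61, against 2.88; 0 genes were called in opposite directions. A call in 1 genotype alone (101 increases and 79 decreases in wt, 201 and 173 in R140Q) does not by itself show a difference, which was tested above.

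**Figure D3:**
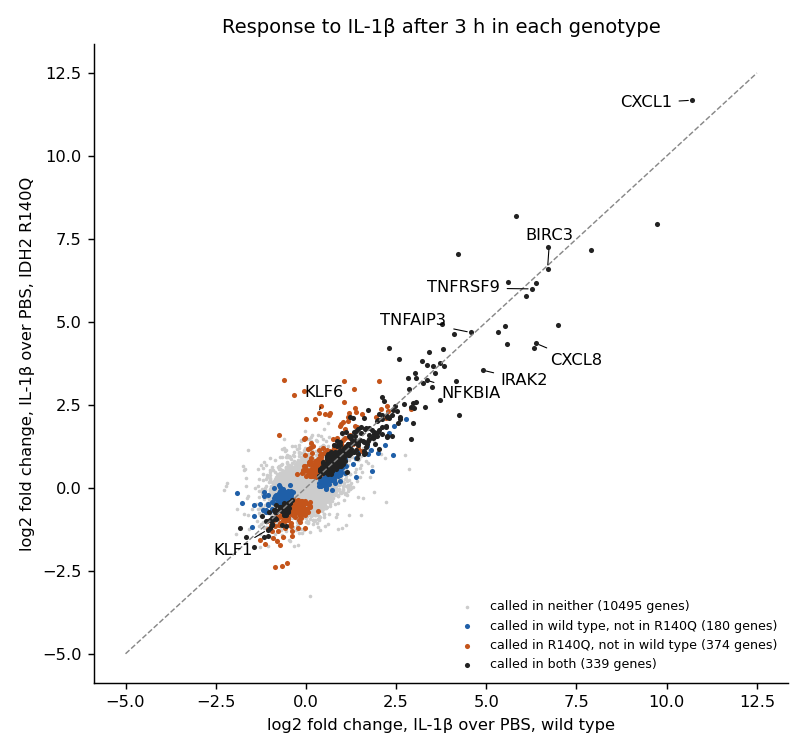
Log2 fold change of IL-1β over PBS in R140Q (vertical) against wt (horizontal) for 11388 genes; colour gives where a gene was called and the dashed line equal responses. NFKBIA (3.34 and 3.24) and TNFAIP3 (4.57 and 4.68) lie near the line and KLF6 (0.36 and 2.25) above it; the place of CXCL1 rests on 1 count in PBS in each genotype and depends on the prior count.

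In single cells, RNA of NF-kB genes was seen more often with IL-1β. With each cell thinned to 1000 UMIs, a UMI of NFKBIA was seen in 25.7% of wt and 30.5% of R140Q cells with IL-1β (group means, n = 2) against 3.50% and 4.30% in PBS, and a UMI of any NF-kB list gene in 93.1% and 95.1% against 65.6% and 68.9%. ICAM1 was seen in 29.7% and 32.2% against 3.80% and 3.94%, TNFAIP3 in 11.3% and 12.2% against 0.693% and 0.506%, and CXCL8 in 7.61% and 10.1% against 0.0878% and 0.379%. BIRC3 was seen in 7.45% of wt and 14.7% of R140Q cells with IL-1β, and without thinning in 14.9% and 19.1%. Without thinning, 1 of 1276 and 7 of 2056 wt PBS cells held a UMI of BIRC3, and 7 of 2337 and 10 of 3033 R140Q PBS cells. In the model over summed counts the BIRC3 responses differed by −0.09 (log2, interval −0.99 to 0.81). KLF6 was seen in 7.52% (exact 95% interval 6.33 to 8.87) and 5.995% (4.95 to 7.18) of cells in the R140Q IL-1β libraries, and in 2.53% (1.55 to 3.87) and 1.68% (1.05 to 2.53) in the wt IL-1β libraries. At 2000 UMIs per cell the KLF6 shares were 10.2% (5.2 to 17.5) and 9.89% (7.06 to 13.4) in R140Q against 5.06% (3.02 to 7.87) and 4.2% (2.97 to 5.74) in wt, with exact intervals that overlap except between the replicates numbered 2. The shares with NFKBIA at that depth were higher, 44.1% in both wt IL-1β libraries and 38.9% and 49.2% in the R140Q ones. IL-1β genes were also present in barcodes with few UMIs, and the share of cells that free RNA would give with IL-1β was not measured.

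The genotype comparison in PBS asks how the lines differ before stimulation. TPSB2, HDC, CA1 and HBB were higher in R140Q cells, and IGF2BP1, HSPD1 and HSPE1 were lower. TPSB2, a mast cell tryptase (ENSG00000197253.13, chromosome 16, 1227272 to 1230184), stood at 5.95 ± 0.912 CPM in wt and 38.7 ± 4.96 in R140Q cells (6.29-fold, log2 2.65 ± 0.19, adjusted p = 4.35e-09). CA1, an erythroid carbonic anhydrase, was 3.69-fold higher (146 ± 1.96 to 538 ± 50.9 CPM). IGF2BP1, a fetal RNA-binding protein (ENSG00000159217.9, chromosome 17, 48997412 to 49055650), went from 43.7 ± 8.11 CPM in wt to 0.808 ± 0.364 in R140Q (log2 −5.70 ± 0.31, adjusted p = 5.19e-11).

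There were 852 genes called in PBS, 434 higher and 418 lower in R140Q cells. The other leading increases were the non-coding gene AC079466.1 (log2 4.23), CXCL8 (2.99 ± 0.32, 7.95-fold), CLCA1 (2.07), the granule protein PRG2 (1.90), embryonic haemoglobin HBE1 (1.84), CAV1 (1.76), LRRN3 (1.42) and DDIT4 (1.28). The difference of CXCL8 rests on few cells. Without thinning, 11 of 2337 and 18 of 3033 R140Q PBS cells held a CXCL8 UMI, and 3 of 1276 and 5 of 2056 wt PBS cells. The other leading decreases were LGALS3BP, a secreted galectin ligand (−3.88, 84.4 ± 2.13 to 5.73 ± 0.329 CPM), MAGEA12 (−2.95), HSPE1 and HSPD1, the mitochondrial chaperonins (−1.28 ± 0.10 and −1.20 ± 0.10), MS4A4A (−1.18) and CPNE1 (−1.03). OSER1 and MOB4 stood at 0.501 and FTLP3 at 0.5 of the wt level. The call of HBE1 ended without R140Q PBS replicate 2 (1.13, adjusted p = 0.156) and without wt PBS replicate 2 (0.95, 0.136). That of the pseudogene FTLP3 ended without R140Q PBS replicate 1 (adjusted p = 0.0699) or 2 (0.373), R140Q IL-1β replicate 1 (0.0612) or 2 (0.0623), or wt PBS replicate 1 (0.265). The count fell to 352 without R140Q PBS replicate 1, 232 without R140Q PBS replicate 2 and 330 without wt PBS replicate 2.

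**Figure D4:**
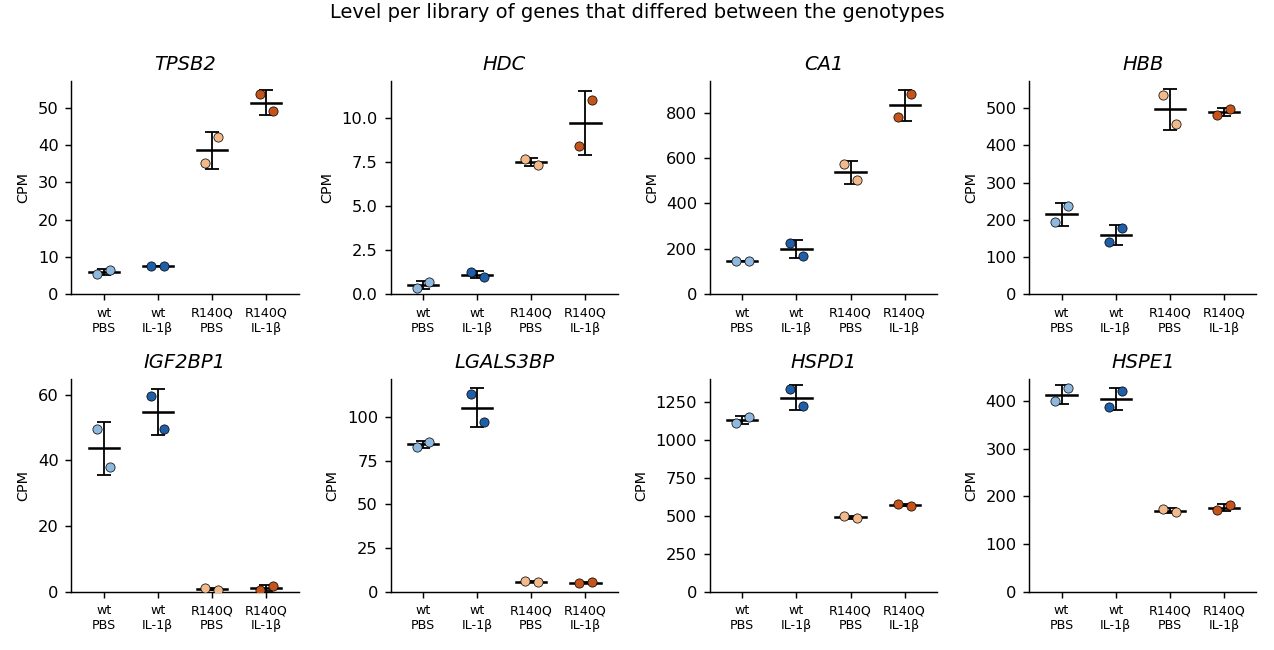
Level in CPM (vertical axes, linear, from 0) of 8 genes in the 4 groups; points are the 2 libraries of a group, the bar is their mean and the whisker their SD. In PBS, TPSB2 (5.95 against 38.7), HDC, CA1 and HBB were higher in R140Q cells, and IGF2BP1 (43.7 against 0.808), LGALS3BP, HSPD1 and HSPE1 were lower.

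Of 8 mast cell and basophil genes tested, 5 were higher (6 adjusted over the list alone, camera adjusted p = 2.71e-15), the only list that held with an estimated correlation (0.0271): TPSB2, PRG2, HDC (histidine decarboxylase, 3.69) and ENPP3 (2.55) led it. Of 20 cytokines and chemokines 8 were higher (8 adjusted over the list alone, 4.92e-06, adjusted p = 0.0608 with an estimated correlation), among them CXCL8, LIF (1.24) and TNFSF10, which encodes TRAIL (1.03). Of 30 ATF4 and unfolded protein response genes 7 were higher and 1 lower (10 and 1 adjusted over the list alone, 5.28e-05, adjusted p = 0.0608 with an estimated correlation), with the amino acid enzymes CTH (0.96) and PSAT1 (0.73) and with CHAC1 (1.12), whose call ended without R140Q PBS replicate 2 (adjusted p = 0.104). In cholesterol synthesis 3 of 25 were lower (3 adjusted over the list alone, 0.000942, adjusted p = 0.0894 with an estimated correlation). Nuclear oxidative phosphorylation had 4 of 40 lower (4 adjusted over the list alone, 0.00614, adjusted p = 0.6 with an estimated correlation). Heat shock had 3 of 21 lower and 1 higher (3 and 1 adjusted over the list alone, 0.01, adjusted p = 0.267 with an estimated correlation). The erythroid list had 5 of 38 higher and 2 lower (6 and 2 adjusted over the list alone, 0.03, adjusted p = 0.238 with an estimated correlation), with CA1, the haemoglobins HBB (1.20) and HBG1 (0.79).

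The other tested lists had camera adjusted p-values from 0.0645 to 0.795, and that of dioxygenases had a median of −0.02 and a mean of −0.01 beside a test up. IDH2 itself (ENSG00000182054.9, chromosome 15, 90083045 to 90102504) stood at 38.1 ± 2.78 CPM in wt and 26.9 ± 5.92 in R140Q cells (log2 −0.53 ± 0.15, adjusted p = 0.038), a call made in 11 of 18 alternatives (adjusted p from 0.00851 to 0.493). It was lost with DESeq2 (0.375), with libraries thinned (0.236), at 2000 UMIs (0.0857), without R140Q PBS replicate 2 (0.493), without wt PBS replicate 2 (0.309) and without either R140Q IL-1β library (0.063 and 0.0634). IDH1 stood at 0.04 (adjusted p = 0.885), NFKBIA at 0.30 (0.209) and TNFAIP3 at 0.15 (0.8). IL1RAP stood higher, 13.7 ± 0.753 to 23.03 ± 2.437 CPM (log2 0.77 ± 0.18, adjusted p = 0.0112), a call made in 14 of 18 alternatives (adjusted p from 0.00209 to 0.192). It was lost with DESeq2 (0.165), with libraries thinned (0.192), and without R140Q PBS replicate 2 (0.186) or wt PBS replicate 2 (0.155). Among markers of other cell types, the T-cell genes CD4 (0.99, higher) and CD3D (−0.84, lower) moved apart (1 up and 2 down adjusted over the list alone). The call of CD3D ended without R140Q PBS replicate 2 (adjusted p = 0.116) or wt PBS replicate 2 (0.194). The 4 fibroblast and epithelium genes did not pass (0 adjusted over the list alone).

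With IL-1β present, the genotype comparison asks which of these differences stimulated cells share. KLF6 was higher in R140Q cells (log2 2.16 ± 0.19, adjusted p = 1.6e-07), as were TPSB2 (2.78 ± 0.22), CXCL8 (0.98 ± 0.11) and CXCL1 (0.85 ± 0.12), while IGF2BP1 (−5.52 ± 0.36) and the chaperonin HSPD1 (−1.16 ± 0.10) were lower. NFKBIA (0.20, adjusted p = 0.341), TNFAIP3 (0.26, 0.237), IDH2 (−0.41, 0.266) and IL1RAP (0.32, 0.472) did not pass. TPSB2, IGF2BP1, HSPD1 and CXCL1 were named here after their values were seen. The genotypes differed in 503 genes, 282 higher and 221 lower in R140Q cells. Of these, 163 increases and 154 decreases were also called in PBS, against 10.7 and 8.11 for independent sets. The count fell to 163 without R140Q IL-1β replicate 1 and to 130 without R140Q IL-1β replicate 2.

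Mast cell and basophil genes (5 of 8 higher, 7 adjusted over the list alone, camera adjusted p = 4.41e-16, 0.0246 with an estimated correlation) held, as did cytokines and chemokines (8 of 20 higher and 1 lower, 10 and 1 adjusted over the list alone, camera adjusted p = 8.75e-09, 0.034 with an estimated correlation). They were the 2 of 11 called lists that did so. Of 30 ATF4 genes 7 were higher (7 adjusted over the list alone, camera adjusted p = 2.85e-05, adjusted p = 0.055 with an estimated correlation). Of 36 NF-kB targets 6 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.000168, adjusted p = 0.0811 with an estimated correlation). Of 40 oxidative phosphorylation genes 1 was lower (2 adjusted over the list alone, camera adjusted p = 0.00215, adjusted p = 0.621 with an estimated correlation). Of 30 immediate early genes 3 were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.00378, adjusted p = 0.157 with an estimated correlation). Of 25 DNA methylation genes 2 were lower (4 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.191 with an estimated correlation). Of 18 GM-CSF signalling genes 2 were higher (2 adjusted over the list alone, camera adjusted p = 0.0336, adjusted p = 0.191 with an estimated correlation). Of 21 heat shock genes 2 were lower (3 adjusted over the list alone, camera adjusted p = 0.0415, adjusted p = 0.412 with an estimated correlation). Of 19 p53 targets 2 were higher (2 adjusted over the list alone, camera adjusted p = 0.0421, adjusted p = 0.198 with an estimated correlation). Of 38 erythroid genes 6 were higher and 2 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.0421, adjusted p = 0.198 with an estimated correlation). Median and mean differed in sign for heat shock (0.03 and −0.09, test down) and the erythroid list (−0.02 and 0.17, test up). They also differed among lists not called for myeloid, glycolysis, apoptosis and NRF2 genes, where the mean and the test were up, while the megakaryocyte test was down with both positive. As averages over 4 libraries against 4, the IL-1β effect called 1604 genes (948 higher) and the genotype effect 1800 (960 higher). Without R140Q IL-1β replicate 2 the former fell to 1026, and without R140Q PBS replicate 2 the latter fell to 1039.

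Genes that differed between the genotypes lay together along chromosomes, most clearly on chromosome 20. Of 116 runs of 50 neighbouring expressed genes, 9 in PBS and 8 with IL-1β lay beyond the random sets, against 0.116 by chance in each, and 7 did so in both with the same sign. The runs lower in R140Q cells lay on chromosome 20 from 31605283 to 43464247 (median log2 −0.50 in PBS and −0.47 with IL-1β) and from 43590931 to 62143440 (−0.50 and −0.50), and on chromosome 19 from 38915266 to 45863290 (−0.17 and −0.24) and from 46346994 to 50418016 (−0.26 and −0.27). The higher ones lay on chromosome 14 from 67359997 to 93207094 (0.15 and 0.19) and from 93207056 to 105932642 (0.24 and 0.20). Another higher run lay on chromosome 8 from 73780097 to 116766925 (0.14 and 0.14). Over the 100 genes of the chromosome 20 stretch the R140Q level was 0.71 of the wt level in PBS (median log2 −0.50, interval −0.56 to −0.44), 96% of the genes lay below 0, and the IL-1β effect had a median of 0.02. The stretch took 1.24 to 1.25% of UMIs in the 4 R140Q libraries and 1.66 to 1.67% in the 4 wt libraries. It holds DNMT3B, a DNA methyltransferase (−0.87 in PBS), and ASXL1 (−0.76), which both count in the DNA methylation list. With IL-1β they stood at −1.16 and −0.74, and they were the members of that list called lower there. Of 826 genes called in PBS on chromosomes 1 to 22, 139 lay in these 7 runs, which held 634 of about 10980 genes tested there. Counting the calls of the main fit without the genes of the runs gave 713 in PBS, 415 with IL-1β and 1561 for the average effect. This count was chosen after seeing the data, and no new fit was made for it.

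**Figure D5:**
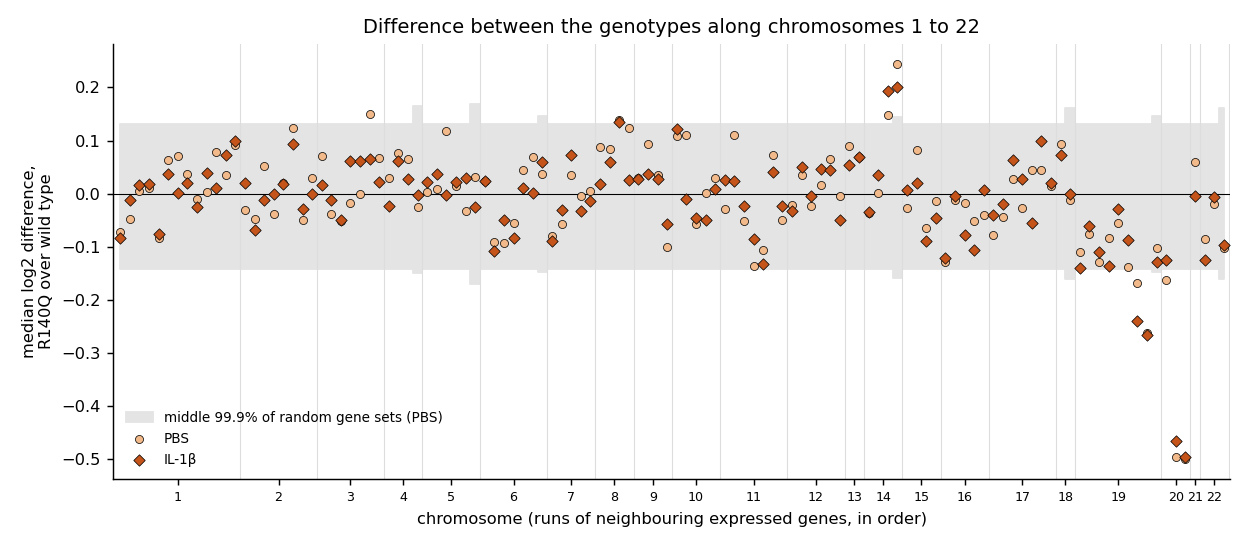
Median log2 difference of R140Q over wt (vertical) in each of 116 runs of neighbouring expressed genes along chromosomes 1 to 22 (horizontal), in PBS (circles) and with IL-1β (diamonds); the grey band holds the middle of 10000 random gene sets in PBS, leaving the outer 0.1%. The chromosome 20 runs lie at −0.50 and −0.50 in PBS and at −0.47 and −0.50 with IL-1β.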

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

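The tests of library depth and handling stress for KLF6, the test of GC content and the tests of why more genes were called in R140Q cells were chosen only after the result was seen, and so was the scan along chromosomes itself.

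KLF6 stood out because its IL-1β responses differed between the genotypes, by 1.89 ± 0.28 (log2). With every library thinned to the smallest, the difference was 1.90 ± 0.361. The call ended (adjusted p = 0.181, against a range of 4.71e-09 to 1 over 17 alternatives) because the error grew from 0.28 with fewer counts. Thinning whole libraries leaves the expected ratios of CPM unchanged, so the kept size cannot decide whether depth contributes. At a minimum of 2000 UMIs, with fewer cells, the difference was 1.36 and the call ended too. A part of depth in the difference stays open. Handling stress in the R140Q IL-1β libraries would move other immediate early genes about as much, and the median difference of 15 such genes was 0.12 (interval −0.06 to 0.15). A small group of cells with many KLF6 copies cannot be told apart from a rise in most cells: 5.995% of cells (exact lower bound 4.95) held a UMI in the lower of the R140Q IL-1β libraries, but the bound set for this test was wrong, because the mean excess over wt was 4.66% of cells, which a group that small could supply. A genotype effect on KLF6 stays open as a hypothesis: the mutation and the line that carries it cannot be separated here, and the call rests on R140Q PBS replicate 1 (adjusted p = 0.149 without it), R140Q IL-1β replicate 1 (0.0914) and wt PBS replicate 2 (0.0938).

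Genes that differ between the genotypes lay together on chromosomes. A candidate explanation is that the lines differ in chromosome copies, which predicts runs that recur in both treatments: 7 of 116 runs did, with 0.116 expected by chance in each treatment, and in the chromosome 20 stretch the R140Q level was 0.71 of the wt level. For the chromosome 20 stretch alone GC content was tested, and argued against: 470 genes elsewhere matched on GC content and level had a median of 0.00109 (interval −0.03 to 0.02) in PBS, against −0.50 in the stretch. Whether copies account for every genotype call cannot be told apart. After the median of their run was subtracted, 20 of 5902 genes, IGF2BP1 and TPSB2 among them, had a difference beyond 1 (log2). BCL2L1 and TPX2 passed 1 only through the subtraction, from average genotype effects of 0.67 and 0.78. The bound set for this test was wrong, because copy changes smaller than a run remain. Of the 20, 5 lie side by side (BCL2L1 and TPX2, HSPD1, HSPE1 and MOB4). DNA was not measured, a direct effect of mutant IDH2 on these genes was not tested, and a regional change of chromatin stays open.

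More genes were called for IL-1β in R140Q than in wt cells, 713 against 519, a ratio of 1.37. The order turned at 2000 UMIs (221 against 292). That minimum left 108 and 374 cells in the R140Q IL-1β libraries, against 356 and 882 in the wt ones. The order also turned without any 1 of the R140Q libraries, and it stayed without any 1 of the wt libraries. Each such fit leaves 1 library in a group of 1 genotype, so these fits cannot decide the order. Thinned to the smallest library the counts were 383 and 309, a ratio of 1.24, which falls between the bounds set for depth, so depth cannot be told apart from other causes. Larger responses were not seen in the NF-kB list, where the mean difference over 36 genes was −0.012 (interval −0.21 to 0.19). The ratio of chi-square to degrees of freedom between replicates was 1.72 and 2.54 in the R140Q groups against 3.76 and 3.62 in the wt groups. That ratio also grows with the number of UMIs. With each genotype fitted alone, 1354 genes were called in R140Q and 300 in wt. The main fit shares 1 estimate of the spread over all groups, so smaller spread in R140Q libraries gives them no smaller error there. Whether spread contributes to the order of 713 and 519 cannot be told. The wt count fell to 245 without wt PBS replicate 2.

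RNA of the 10 largest increases was also present in barcodes with 5 to 100 UMIs, which no comparison used. It stood at 1304 ± 12.02 CPM in wt with IL-1β against 74.3 ± 1.09 in PBS (n = 2 each), and at 1614 CPM in the 1 R140Q IL-1β library with such barcodes against 106 ± 7.92 in PBS (n = 2), beside 1563 and 2221 CPM in cells with IL-1β.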

How the results depend on the processing

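All alternatives here were chosen before the values were seen, except the one at the end. Median-of-ratios size factors, at most 20% mitochondrial UMIs and doublets left out kept each gene count within 1.5 times its value, and so did no filter and 500 UMIs except for the difference of responses. With DESeq2 the counts were 266 for IL-1β in wt, 337 in R140Q, 285 and 206 for the genotype in PBS and with IL-1β, and 985 and 1038 for the average IL-1β and genotype effects. At 2000 UMIs, with fewer cells, they were 292, 221, 323, 131, 684 and 691. Thinned to the smallest library, with fewer counts, they were 309 and 383 for IL-1β in wt and R140Q, 328 for the genotype in PBS, and 979 and 946 for the averages. With a replicate block they were 872, 1099, 1351 and 826 for IL-1β in wt, in R140Q and the genotype in PBS and with IL-1β. Same-numbered libraries deviated together with correlations, across genes, of 0.024 to 0.33 over 6 pairs of groups, with 4 above 0.1. Replicate 2 also held more UMIs in cells than replicate 1 in each group. The numbers may therefore mark something shared, but the labels do not say so, and the block stayed an alternative only. With only the libraries compared, the counts of called genes for IL-1β were 300 in wt and 1354 in R140Q. The difference of responses, 1 gene, had 3 genes with no filter, 2 at 500 UMIs, 0 at 2000 UMIs, 0 thinned, 2 with a replicate block (KLF6 and CXCL8, −2.02, adjusted p = 0.0343) and 2 at an adjusted p under 0.1. Leaving out each library gave 245 to 571 for wt, 274 to 1003 for R140Q, 0 to 16 for the difference, 232 to 1190 and 130 to 535 for the genotype in PBS and with IL-1β, and 1026 to 1625 and 1039 to 2067 for the averages. The difference had 0 genes without R140Q PBS replicate 1, R140Q IL-1β replicate 1 or wt PBS replicate 2, and 16 without wt IL-1β replicate 2. Lists called went from 9 to 3 in wt and 8 to 3 in R140Q with an estimated correlation, and to 16 and 16 with fry, and in R140Q to 14 with a replicate block. For the genotype they went from 7 to 1 in PBS and 11 to 2 with IL-1β with an estimated correlation, and to 12 with fry in PBS. Apart from fewer cells, counts or libraries, the cause was not tested. Of 8661 values for 489 single-gene results, 7767 kept direction and side of the threshold, 668 lost the call, 226 gained it and 0 reversed, and of 405 values for 135 list results these were 339, 33, 33 and 0. In simulated data of this size, 2-fold planted differences of responses at 20 CPM or more were recovered in 84.8% of cases and 1.5-fold ones in 21.4%. Those data held 50 changed genes at each planted fold, which eases the adjusted threshold. The shares therefore do not give the recovery where few genes differ, as here. Leaving out genes in the differing chromosome runs from the calls of the main fit, without a new fit, gave 713, 415 and 1561 genotype calls. That was chosen after seeing the data.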

Other observations

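The close reading of the chromosome 20 boundary and of the neighbours of HSPD1 was chosen only after the result was seen, and the splits of the libraries were chosen before.

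The splits of the libraries cannot exclude chance as the source of either average effect. Many of them do not balance the other factor, whose libraries are not interchangeable. Fewer splits remain when it is balanced, so a share of 1 of 34 is not a p-value. Of the 34 splits of the 8 libraries into 4 and 4 that could be fitted (of 35, the split equal to the other factor could not be), 1, the real one, called as many as 1604 genes for IL-1β, and the highest other called 0. For the genotype it was likewise 1 of 34, with 1800 genes against a highest other of 0. The other splits leave the real effect in the spread between libraries, which lowers their counts, so the distance to 0 does not measure how strong the effects are.

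On chromosome 20 the genotype difference in PBS turned from higher to lower within a short stretch. HM13 (log2 0.78), ID1 (0.34), BCL2L1 (0.66) and TPX2 (0.86) were on the higher side, and from PDRG1 at 31944342 on, PDRG1 (−0.83), PLAGL2 (−0.92), NOL4L (−0.98), DNMT3B (−0.87) and MAPRE1 (−0.76) were on the lower side. On chromosome 2, the adjacent genes HSPD1 and HSPE1 stood at −1.20 and −1.28 and their neighbour MOB4 at 0.501 of the wt level, beside SF3B1 (−0.01), COQ10B (−0.16) and MARS2 (−0.13).

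Clustering of the cells at resolution 0.5 gave 7 groups (5 at 0.2 and 12 at 1.0), with no test between libraries. A group marked by CXCL1, CXCL3, CXCL8, CXCL2 and TNFRSF9 held 51.3 to 62.4% of cells in the IL-1β libraries and 0.146 to 0.314% in the PBS libraries. Because that group takes over 50% of cells with IL-1β, the other shares depend on whether its cells are counted. A group marked by HBZ, HBG2, HBG1, HBB and ALAS2 held 29.04 to 39.03% of all cells in PBS and 12.3 to 19.9% with IL-1β, but 29.08 to 39.15% and 30.9 to 40.92% of the cells outside the chemokine group. A group marked by PRG2, CALB1, CCL5, F13A1 and TCN1 held 3.36 to 3.59% of all cells in PBS and 4.14 to 4.37% with IL-1β in R140Q libraries, and 1.72 to 1.75% and 1.89 to 1.91% in wt libraries. Among cells outside the chemokine group it held 3.372 to 3.602% in PBS and 8.962 to 9.488% with IL-1β in R140Q libraries, and 1.73 to 1.754% and 4.798 to 5.034% in wt libraries. A group marked by CDK1, UBE2C, ESAM, NDUFAB1 and DDAH2 held 14.67 to 33.61% of all cells in PBS and 1.09 to 11.05% with IL-1β. Of the cells outside the chemokine group it held 14.71 to 33.66% and 2.497 to 27.83%. Its cells had a median of 2476 UMIs, the highest of the groups, and whether depth enters it was not tested. Phase scores put 64.9 to 72.1% of cells in G2 and M and 10.41 to 18.15% in G1 in each library, with cells thinned to 1000 UMIs. Without thinning the ranges were 71.61 to 86.72% and 5.739 to 15.86%. The phase shares thus moved with depth, and they are not read by themselves as the share of cells in a phase.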
